A study of Mus musculus with 51 samples.

How the data were processed

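Per the labels, total RNA was extracted with a silica column kit from tissue kept in a stabilising solution or, for adipose tissue, frozen in liquid nitrogen, and libraries were made with PrepX reagents. The values used are gene-level CPM tables deposited by the authors, 1 per tissue, rounded to 1 decimal. Per the submitters' processing notes, reads were counted with HTSeq (version not given) on the mouse genome build GRCm38; the aligner, the annotation release and whether counting used the strand are not given in the sources used here. Reads of antisense or overlapping genes and of near-identical family members (defensins, Serpina1 and Serpina3, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Ugt2b, Akr1c, Acot, orosomucoids, globins, Slc6a20) may therefore be divided uncertainly. Each deposited table holds only genes with at least 1 CPM in as many libraries as its smaller group has, as checked on every gene. In ileum and WAT, 339 and 374 repeated lines with identical values were dropped, and 2 lines in ileum and 6 in liver without a gene identifier were left out. Identifiers were matched to the GENCODE annotation of GRCm38 given with the data for coordinates, symbols that a spreadsheet had altered, and exon lengths.

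Each sample was assigned from its title and surgery label. Replicate numbers in the titles name different animals in the sham and RYGB groups, as the animal codes in the descriptions show. The p-values measure the spread between these animals.

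The choice of tests, lists, named genes and alternative settings was made before the data were examined, on the assumption that the tables would hold read counts. As they hold CPM, the fallback written for that case was used: per tissue, limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust options) on log2(CPM + 1), with surgery as the only term and the libraries of that tissue only, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low CPM. Duodenum and jejunum were compared in 1 model with the animal as a block, a segment term and a segment by surgery term, over the animals that gave both segments; both tables are CPM, so their scale is shared. A set of 51 gene lists covering pathways and cell types, markers of contaminating cells included, was tested with camera (preset correlation 0.01, and again with the correlation estimated per list) and fry in those tissues where each was judged to apply, with at least 3 measured members and adjustment over the lists of the tissue. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.

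The named genes follow a fixed rule. It takes, per tissue and direction, the 10 genes with the largest log2 fold change among those with an adjusted p below 0.05, a mean CPM of at least 5, no overlap between the groups and a symbol that is not a predicted-gene name. It adds up to 4 members with the smallest adjusted p and up to 2 with the highest CPM of each list with a test or with at least 3 members past the threshold, genes past the threshold in the same direction in 3 or more tissues, the 10 genes with the smallest p where fewer than 10 pass, and 1 set of genes named whatever their p (Igf1, Ghr, Hif1a and others that fit the tissue). The text names a part of the genes the rule allows.

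The fits were tested on simulated data with the means and spread of the real genes of each tissue, with 200 genes changed. Of 100 genes changed by 2 on the log2 scale, 85 were recovered in duodenum (10930 genes), 87 in jejunum (11021 genes), 27 in ileum (12041 genes), 44 in liver (10285 genes), 96 in WAT (12690 genes) and 88 in muscle (11594 genes); of 100 changed by 1, the numbers were 42, 41, 0, 2, 60 and 42. In the simulated comparison of segments (10663 genes), 76 of 100 genes with a difference of 2 were recovered. False calls were 8 of 135, 3 of 131, 1 of 28, 1 of 47, 7 of 163 and 6 of 136 in the tissues in that order, and 12 of 184 for the segments. Each gene was drawn independently from a normal distribution, so these data hold no atypical or contaminated library and do not show how the fits behave with one.

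Alternatives tried were median-of-ratios scaling of the CPM, a pseudocount of 0.1 for the named genes, the replicate number as a block, each library left out in turn, and, added after seeing the data, that pseudocount for the counts, that scaling for the lists, a mean CPM of at least 5, limma's library weights, a depth term in liver, removal of each library's lowess trend with exon length, and the duodenum without libraries rich in pancreatic transcripts. Whole read counts could not be recovered for most libraries, so no count-based test was run. Library pairs were checked for identical values, and there were 0. Within groups the libraries correlated at 0.793 to 0.99 across genes on the log2 scale.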

Results

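Messenger RNA was profiled in 51 libraries from 6 tissues of male C57Bl6 mice made obese by diet, 9 weeks after Roux-en-Y gastric bypass (RYGB) or a sham operation. In RYGB, food passes from a small stomach pouch straight into the jejunum, so that the duodenum no longer receives it. Both groups went through an elemental liquid diet before returning to high-fat food, and the sham mice ate restricted rations so that their weight followed that of the RYGB mice. Each comparison therefore asks what differed between RYGB mice and food-restricted sham mice at similar body weight, after an overnight fast. The operation and the restricted rations of the sham mice cannot be told apart in this design. The libraries were 5 sham and 4 RYGB for duodenum, 5 and 4 for jejunum, 5 and 2 for ileum, 4 and 5 for liver, 5 and 4 for white adipose tissue (WAT), and 4 and 4 for gastrocnemius muscle. They carry 10 animal codes, 5 per operation, and most animals gave several tissues. Gut samples were villi scraped after cold EDTA; which surgical limb a jejunal sample came from is not given in the sources used here. For the muscle RYGB libraries 1 label field names a sham source while the title and the surgery field name RYGB, and the latter were followed.

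The deposited values are CPM, counts scaled to the total of each library, and hold no read totals. The listed genes summed to between 978879 and 993560.1 CPM per library. Of the 9 liver libraries, 5 hold values in steps that imply 4220000 to 5060000 counted reads; in the other 46 libraries the depth is unknown beyond 1 read being worth less than the last printed decimal. Log2 fold changes are RYGB minus sham on the log2(CPM + 1) scale with their standard errors (SE), CPM values are means ± SD, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over all genes of the tissue. "Rose" and "fell" are used of genes with an adjusted p below 0.05. Lists of genes were compared with all other genes of the tissue by camera with a preset correlation. Results of fry, run beside it, are given for a part of the lists only. None of the 66 list calls it made in the 6 tissues held with an estimated correlation, whose adjusted p stands beside each call.

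**Figure D1:**
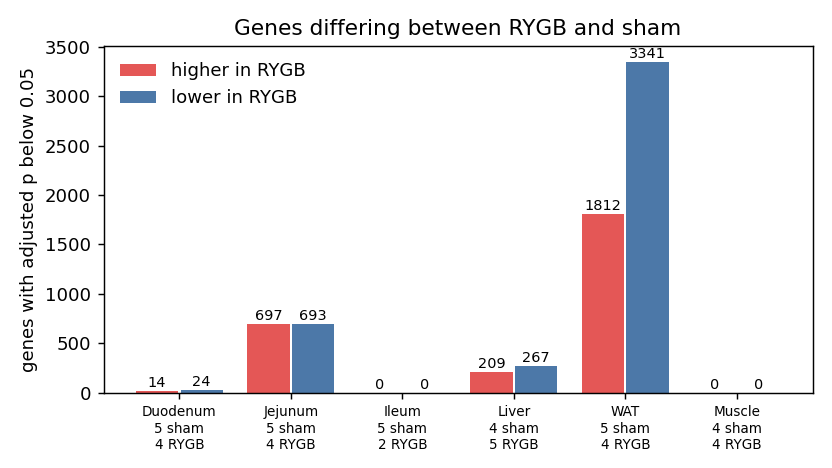
Bars give the number of genes (vertical axis) with an adjusted p below 0.05 in each tissue (horizontal axis, with the number of libraries), higher in RYGB in red and lower in blue. WAT has the most, with 1812 and 3341, and ileum and muscle have 0.

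In the duodenum, the segment the bypass excludes from food, 24 genes fell and 14 rose after RYGB (n = 5 sham and 4 RYGB libraries). Akp3, an intestinal alkaline phosphatase of the duodenal brush border, averaged 3206 ± 1993 CPM in sham and 79.98 ± 108 CPM in RYGB mice (log2 fold change −6.05 ± 0.85, adjusted p = 0.0372). Scarb1, a lipoprotein receptor, fell from 162 ± 69.4 to 8.33 ± 5.31 CPM (−4.18 ± 0.45, adjusted p = 0.00576), and Otop3, a proton channel, from 241 ± 96.0 to 20.8 ± 8.71 CPM (−3.47 ± 0.34, adjusted p = 0.0033). The sugar-phosphate transporter gene Slc37a2 (−3.45), the acyl-CoA synthetase gene Acsl6 (−3.08), the transcription factor genes Meis2 (−2.68) and Foxq1 (−2.28) and the ferritin receptor gene Ncoa4 (−2.07) fell as well. Genes that rose included Prc1 (2.56), Ect2 (1.91) and Mcm2 (1.98), which act in cell division or DNA replication, the lectin gene Itln1 (2.37) and the Paneth cell defensin Defa24 (2.44), 1 of a family of near-identical genes. Akp3 lies on chromosome 1 from 87124973 to 87127912, and Scarb1 on chromosome 5 from 125277087 to 125341094 (GRCm38).

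Of 15 measured genes of iron, calcium and micronutrient absorption, 1 fell and none rose over all genes tested; adjusted over the list alone, 7 fell and 3 rose. The member past the test was Slc46a1, the proton-coupled folate transporter (−1.67 ± 0.28, adjusted p = 0.0372). Slc40a1, the iron exporter ferroportin, stood at 1387 ± 985 CPM in sham and 75.7 ± 102 CPM in RYGB mice (−4.97 ± 0.95, adjusted p = 0.057), and the ferric reductase gene Cybrd1 at 43.2 ± 46.9 and 0.95 ± 0.929 CPM (adjusted p = 0.065). The list was lower than other genes by camera (adjusted p = 0.000299), with an adjusted p = 0.108 with an estimated correlation. Fry called this list alone in the duodenum (adjusted p = 0.00474). It gave an adjusted p = 0.253 for the proliferation, interferon and endothelial lists and 0.413 for dietary lipid absorption. Of 23 genes of dietary lipid absorption 2 fell, Scarb1 and the apolipoprotein gene Apoc3 (−1.42), and adjusted over the list alone 3 did. The abundant Apoa4 (13550.0 ± 6423 and 10050.0 ± 4850.0 CPM) and the cholesterol transporter gene Npc1l1 (adjusted p = 0.0748) did not pass. That list was also lower by camera (adjusted p = 0.00244; adjusted p = 0.615 with an estimated correlation). Of 22 genes of brush-border digestion and transport none passed in limma, 1 rose and 1 fell adjusted over the list alone, and camera did not call the list (adjusted p = 0.0926).

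Of 17 proliferation genes 1 rose over all genes, Mcm2, and 12 adjusted over the list alone (camera adjusted p = 3.95e-05; adjusted p = 0.647 with an estimated correlation). Top2a stood at 4.68 ± 1.81 and 84.2 ± 98.1 CPM (adjusted p = 0.102) and Ccna2 at 1.22 ± 0.303 and 34.5 ± 30.9 CPM (adjusted p = 0.0866). Of 8 intestinal stem cell genes 0 passed, and 3 rose and 1 fell adjusted over the list alone. Of 13 Paneth and antimicrobial genes 1 rose, and 4 rose and 2 fell adjusted over the list alone. Camera called neither list (adjusted p = 0.1005 and 0.0926). Whether the share of crypt cells in the scrapings differed between the groups was not tested. The interferon response list (23 genes, 0 past the test, 2 fell adjusted over the list alone), the T and NK cell list (14 genes, 0 and 0), the endothelial list (7 genes, 0 and 5 fell) and 4 markers of stomach and Brunner glands (0 and 2 fell) were lower by camera. Their adjusted p with an estimated correlation was 0.51, 0.615, 0.51 and 0.51. The clock gene list was lower too (16 genes, 0 past the test; 4 rose and 7 fell adjusted over the list alone), with an adjusted p = 0.51 with an estimated correlation; its member Dbp stood at 60.3 ± 26.6 and 10.1 ± 6.67 CPM (adjusted p = 0.0535) and Arntl at 11.7 ± 5.59 and 42.4 ± 23.9 CPM (adjusted p = 0.0541). Slc5a1, Slc2a1, Hif1a, Ghr, Igf1 and Gcg did not pass the test; Gcg, which encodes proglucagon, stood at 6.42 ± 2.57 and 19.9 ± 9.92 CPM (adjusted p = 0.0629).

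Transcripts of pancreatic acinar cells were high in 4 duodenum libraries, with 0 of 17 members past the test in limma, also adjusted over the list alone. Summed over 17 pancreatic genes they made up 6.04%, 8.87% and 6.1% of the CPM in sham 1, 2 and 3 and 1.52% in RYGB 2, and at most 0.0828% in the other 5 libraries. Pnlip, the pancreatic lipase gene, averaged 9741 ± 9878 CPM in sham and 1110.0 ± 2133 CPM in RYGB mice (adjusted p = 0.455); Cela2a (adjusted p = 0.359) and Cpa1 (adjusted p = 0.388), which encode digestive enzymes, did not pass either. Camera placed this list lower (adjusted p = 1.43e-07; adjusted p = 0.615 with an estimated correlation). Without those 4 libraries, 2 sham and 3 RYGB libraries remained, and limma called 0 genes, with 378 at an unadjusted p under 0.05.

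Limma called 14 genes higher and 24 lower of 10930 (2486 at an unadjusted p under 0.05), and with median-of-ratios scaling 13 and 37. That scaling moved the median log2 fold change of all genes from 0.149 to −0.00667, a scaling shift of 0.16 (CPM minus scaled). Relative to this shift each log2 value given here for the duodenum is lower by that amount. Every library mattered: the 38 calls became 1, 13 and 3 without RYGB 1, 2 and 4, 5, 2, 2 and 4 without sham 1, 2, 3 and 4, 982 without RYGB 3 and 440 without sham 5.

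In the jejunum, most measured genes of cholesterol synthesis rose after RYGB (n = 5 sham and 4 RYGB libraries). Of 24 measured members 18 rose, none fell and 6 did not pass; adjusted over the list alone 20 rose and 1 fell. Mvd, mevalonate diphosphate decarboxylase, rose from 2.44 ± 1.01 to 21.2 ± 8.45 CPM (2.65 ± 0.33, adjusted p = 0.00301), Fdft1, squalene synthase, from 4.74 ± 1.56 to 47.8 ± 26.1 CPM (2.91 ± 0.43) and Cyp51, lanosterol demethylase, from 13.5 ± 3.8 to 265 ± 214 CPM (3.71 ± 0.61). Sqle (3.4), Fdps (2.73) and Lss (2.03) rose too. The median log2 fold change of the list was 1.63 (camera adjusted p = 1.46e-10; adjusted p = 0.418 with an estimated correlation). Of 17 genes of fatty acid synthesis 6 rose and 9 did so adjusted over the list alone, among them Fasn, fatty acid synthase (2.13 ± 0.28), Pklr, pyruvate kinase (1.63 ± 0.22), and the elongase gene Elovl6 (2.05 ± 0.47). Camera gave that list an adjusted p = 0.00403, and an adjusted p = 0.418 with an estimated correlation. Mvd lies on chromosome 8 from 122433601 to 122443422 (GRCm38).

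**Figure D2:**
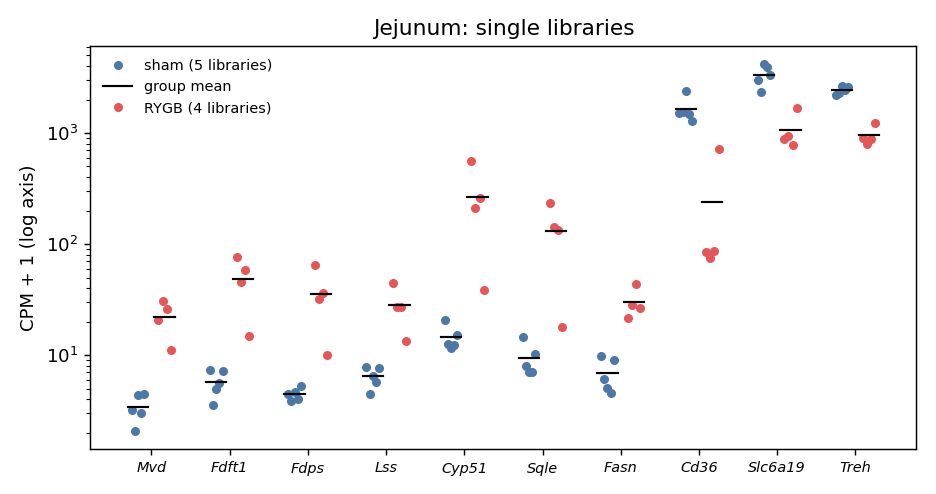
Points are single jejunum libraries, sham in blue and RYGB in red, black lines are group means, and the vertical axis is CPM + 1 on a log scale for the genes named on the horizontal axis. Genes of cholesterol and fatty acid synthesis stand higher in RYGB libraries, and Cd36, Slc6a19 and Treh lower, with mean CPM of Mvd at 2.44 in sham and 21.2 in RYGB libraries.

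Some genes of glucose use rose too in the jejunum. Of 29 glycolysis and HIF1 target genes 11 rose and none fell (14 rose adjusted over the list alone), including the glucose transporter gene Slc2a1 (17.8 ± 7.94 to 73.6 ± 34.2 CPM, 1.92 ± 0.39), Pfkp (1.18), Gpi1 (1.47) and Ldha (1.6), which encode glycolytic enzymes. Camera gave an adjusted p = 1.6e-05, and an adjusted p = 0.574 with an estimated correlation. Hif1a itself did not pass (0.52 ± 0.41, adjusted p = 0.426), nor did Slc5a1, the sodium-glucose cotransporter of the brush border (0.12 ± 0.29, adjusted p = 0.819). Of 33 oxidative phosphorylation genes 6 rose, and 16 adjusted over the list alone, with 32 above 0; examples are Uqcrc1 (1.18 ± 0.23) and Atp5b (0.85 ± 0.19). Of 16 NRF2 target genes 7 rose, and 8 adjusted over the list alone, led by the glutathione peroxidase gene Gpx2 (16.7 ± 5.79 to 921 ± 1033 CPM, 4.54 ± 0.93), the glutathione reductase gene Gsr (2.3) and the transketolase gene Tkt (1.43). Both lists had an adjusted p = 0.574 with an estimated correlation, after camera values of 4.62e-06 and 0.00129.

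Paneth and antimicrobial transcripts were higher in the RYGB jejunum. Of 13 Paneth and antimicrobial genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00379; adjusted p = 0.418 with an estimated correlation). Reg3g, an antibacterial lectin, rose from 182 ± 234 to 2859 ± 2555 CPM (4.23 ± 0.89), the oxidase gene Duox2 from 6.68 ± 6.88 to 1365 ± 1303 CPM (6.41 ± 1.44), Lyz1, a lysozyme, by a log2 value of 2.63 and the protease gene Mmp7 by 3.29. Of other secretory cells, 1 of 12 goblet, 2 of 19 enteroendocrine and 0 of 9 tuft genes rose, and camera called none of these lists (adjusted p = 0.0799, 0.299 and 0.204). The largest increases by the naming rule included Mgat4c, a glycosyltransferase (2.72 ± 1.71 to 125 ± 96.0 CPM, 4.75 ± 0.64), the pancreatic lipase-related gene Pnliprp2 (4.06), Mecom, a transcription factor (3.93), Slc5a8, a monocarboxylate transporter (3.83), and the mucin gene Muc4 (3.47). Of 19 proliferation genes 1 rose, Rrm2, a subunit of ribonucleotide reductase (2.13), and 7 adjusted over the list alone. Camera gave that list an adjusted p = 0.00337, and an adjusted p = 0.645 with an estimated correlation. Fry did not call it (adjusted p = 0.161). Of 8 intestinal stem cell genes 1 rose, also adjusted over the list alone, and 7 were above 0 (camera adjusted p = 0.0799). Whether the share of crypt cells in the villus scrapings differed between the groups was not tested. Gcg rose from 4.52 ± 2.08 to 10.5 ± 3.83 CPM (1.08 ± 0.31, adjusted p = 0.0447), and was not called with median-of-ratios scaling; Slc10a2, the ileal bile acid transporter, rose from 0.72 ± 0.342 to 3.77 ± 2.62 CPM.

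Genes of absorption were among those that fell in the jejunum. Of 22 brush-border digestion and transport genes 8 fell and none rose (12 fell and 2 rose adjusted over the list alone; camera adjusted p = 5.16e-05; adjusted p = 0.418 with an estimated correlation). Fry called that list too (adjusted p = 0.01735). The amino acid transporter gene Slc6a19 fell from 3341 ± 720.1 to 1069 ± 408 CPM (−1.68 ± 0.25), Slc6a20a, a proline transporter with a near-identical neighbour, by a log2 value of −4.11, the trehalase gene Treh by −1.37, the peptide transporter gene Slc15a1 by −1.29 and the aminopeptidase gene Anpep by −1.13. Cd36, a fatty acid translocase on chromosome 5 from 17781690 to 17888801 (GRCm38), fell from 1642 ± 431 to 240.4 ± 320 CPM (−3.51 ± 0.6, adjusted p = 0.00863). It was 1 of 4 genes of 23 for dietary lipid absorption that fell (5 fell and 1 rose adjusted over the list alone), with Abcg5 (−0.65) and Dgat1 (−0.6), while Apob did not pass (adjusted p = 0.185). Cubn, the intrinsic factor receptor (−4.19), and the water channel gene Aqp1 (−4.07) fell further.

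Of 18 xenobiotic metabolism genes 7 fell and none rose, and 8 fell adjusted over the list alone. Examples from multigene families are Ugt2b5 (−3.83), Cyp3a25 (−1.91) and Cyp3a11 (−1.6), and the aldo-keto reductase gene Akr1c19 (−4.0) also fell. Of 11 retinoid genes 4 fell, among them Aldh1a1 (−2.12) and Lrat (−1.69), with 4 fallen and 1 risen adjusted over the list alone. Of 23 fatty acid oxidation and PPARA target genes 4 fell, with Cyp4a10 (−3.76) and Ppara (−1.45), and 5 fell and 2 rose adjusted over the list alone. The first 2 lists were lower by camera (adjusted p = 0.00363 and 0.049; adjusted p = 0.574 and 0.418 with an estimated correlation); the call on retinoid genes was lost without RYGB 3 (0.0606), sham 3 (0.095) or sham 5 (0.0548), and with median-of-ratios scaling (0.0509). Of 23 interferon genes 4 fell, among them Ifit1 (−1.87), and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0462; adjusted p = 0.645 with an estimated correlation), a call lost without RYGB 2 (0.064), RYGB 4 (0.292), sham 1 (0.0851) or sham 5 (0.0654). Of 17 clock genes 6 fell and 2 rose (7 and 3 adjusted over the list alone): Dbp fell from 67.6 ± 24.3 to 7.55 ± 10.2 CPM (−3.53 ± 0.58), Per3 by a log2 value of −2.72, and Npas2 rose (1.16). That list was lower by camera (adjusted p = 0.00742; adjusted p = 0.418 with an estimated correlation). Ghr, the growth hormone receptor, fell from 34.3 ± 6.04 to 6.5 ± 3.89 CPM (−2.35 ± 0.3, adjusted p = 0.00309).

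Limma called 697 genes higher and 693 lower of 11021 in the jejunum. The sum of 1390 became 717 without RYGB 1, 565 without RYGB 3, 2258 without RYGB 4, and 543, 484, 752 and 585 without sham 1, 2, 3 and 4.

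The difference between the segments was tested within the 8 animals that gave both (5 sham and 3 RYGB). Pancreatic transcripts were high in the duodenum libraries of 3 of these sham animals (W11, W12 and W14) and of none of these RYGB animals. No fit without all 3 was made, so the part of this contamination in the difference was not tested. The RYGB difference was higher in jejunum than in duodenum for 56 genes and lower for 200 of 10663 (2170 at an unadjusted p under 0.05), and for 83 and 119 with median-of-ratios scaling. For some genes the RYGB difference was lower in the duodenum: jejunum minus duodenum, it was 6.11 ± 0.77 for Akp3 (adjusted p = 0.00936), 5.91 ± 0.74 for Slc40a1 (adjusted p = 0.00914), 3.33 ± 0.53 for Slc37a2 and 2.2 ± 0.46 for Ncoa4. Cd36 had the opposite sign (−3.58 ± 0.4, adjusted p = 0.00482), as did Cubn (−3.59), Aqp1 (−4.93), Slc6a20a (−3.32), Slc15a1 (−1.31), Akr1c19 (−3.41), Ugt2b5 (−3.17), Cyp3a25 (−2.0) and Cyp4a10 (−3.15). Fdft1 (2.19), Elovl6 (1.82), Pklr (1.74) and Gpi1 (1.41) had the larger RYGB difference in jejunum, while Mvd, Cyp51, Sqle, Fdps, Lss, Fasn, Slc2a1, Pfkp and Ldha did not pass this test. Across genes, which are not independent replicates, the log2 fold changes of the segments gave a Pearson r = 0.202 and a Spearman rho = 0.0839. The counts became 20 and 43 without the RYGB animal R2, 36 and 116 without R5, and 16 and 43, 23 and 66, and 34 and 124 without the sham animals W12, W14 and W3.

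**Figure D3:**
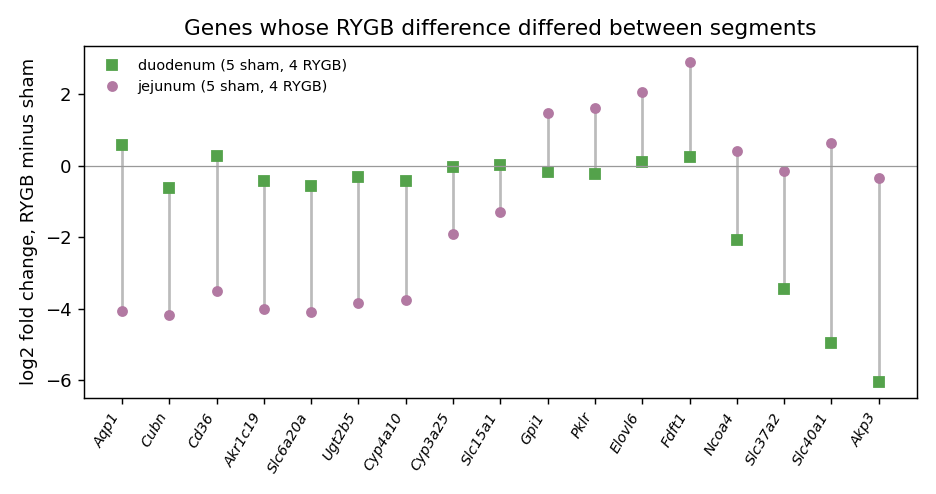
For the genes on the horizontal axis, the vertical axis gives the log2 fold change of RYGB minus sham in duodenum (green squares) and jejunum (purple circles), each from 5 sham and 4 RYGB libraries. The genes are those named in the text whose difference between the segments had an adjusted p below 0.05; Akp3 has −6.05 in duodenum and −0.34 in jejunum.

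In the ileum no gene passed the test in limma (n = 5 sham and 2 RYGB libraries; 438 of 12041 genes at an unadjusted p under 0.05, 0 past the adjusted threshold; 1 gene with library weights). The gene with the smallest p was Fabp1, a fatty acid binding protein on chromosome 6 from 71199827 to 71205023 (GRCm38), at 79.2 ± 22.6 CPM in sham and 372 ± 70.4 CPM in RYGB mice (2.25 ± 0.31, adjusted p = 0.702). The genes next to it included Mt2, a metallothionein (3.3 ± 4.0 and 58.3 ± 3.11 CPM), Adh6a, Dnase1, Mgst1, Tns4 and Itpr2, all with an adjusted p = 0.935. Fgf15, the ileal hormone that represses bile acid synthesis, averaged 168 ± 170 CPM in sham and 16.3 ± 19.4 CPM in RYGB mice (−3.32 ± 1.14, adjusted p = 1.0), and Slc10a2 432 ± 267 and 325 ± 316 CPM. Gcg, Slc5a1, Slc2a1, Igf1, Hif1a and Ghr did not pass. In simulated ileum data, 0 of 100 genes changed by 1 on the log2 scale and 27 of 100 changed by 2 were recovered, so the design could show only large differences.

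Camera placed 12 of 33 lists higher and 4 lower in the ileum, with 0 genes past the test in any of them. Adjusted over the list alone, 2 NRF2 target, 2 glucocorticoid response and 1 lipid absorption gene rose, 1 clock gene fell, and none passed in the other 12 lists. All 25 cholesterol synthesis genes but 1 were above 0 (median 0.5; Hmgcs1 0.91 ± 0.26; adjusted p = 0.419 with an estimated correlation), as were all 33 oxidative phosphorylation genes (median 0.36; adjusted p = 0.57 with an estimated correlation). Lists of unfolded protein response, ATF4 target and proliferation genes were higher (adjusted p = 0.564, 0.57 and 0.665 with an estimated correlation), and the tuft cell, endothelial, smooth muscle and clock lists lower (0.665, 0.665, 0.665 and 0.419 with an estimated correlation). The lists of goblet cell, retinoid, lipid absorption, glycolysis, xenobiotic, NRF2 target and glucocorticoid response genes were higher, with an adjusted p between 0.333 and 0.665 with an estimated correlation. Sham 4 stood apart in this tissue, with a median CPM of 33.9 and a sum of 1238.9 CPM over the 11 measured genes of the pancreatic list. The median difference of that list from the other sham libraries was 0.625 on the log2 scale, so the sum alone does not show acinar contamination. Without sham 4, 28 genes were higher and 18 lower. Without RYGB 1, which leaves a lone RYGB library assumed to vary like the sham group, 1 gene passed. Without sham 4 the lipid absorption list turned its direction (adjusted p = 0.596), and without RYGB 1 the goblet and glycolysis lists turned theirs (0.876 and 0.766). Of the 16 list calls 4 held without RYGB 1, 10 without sham 4, 13 without RYGB 2 or sham 5, and 15 without sham 3. Those lost without RYGB 1 include proliferation (0.363), NRF2 target (0.266), ATF4 target (0.18), clock (0.161) and cholesterol synthesis genes (0.0748). With median-of-ratios scaling the retinoid call was lost (0.105), and with the trend with exon length removed that (0.14) and the xenobiotic and clock calls (0.0506).

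In the liver, genes of the acute phase were among those that rose after RYGB (n = 4 sham and 5 RYGB libraries). Of 19 acute phase genes 5 rose and none fell, 12 rose adjusted over the list alone, and all 19 were above 0. Fga, Fgb and Fgg, the fibrinogen chains, rose from 735 ± 536 to 10750.0 ± 9958 CPM, 1590.0 ± 801 to 9641 ± 6479 CPM and 820.2 ± 620.3 to 12620.0 ± 12910.0 CPM (3.59, 2.46 and 3.72). Orm1, orosomucoid, rose from 25.3 ± 23.9 to 2289 ± 2691 CPM (6.1 ± 1.02, adjusted p = 0.0302), and the hemopexin gene Hpx (4.59), Itih3 (4.59) and the complement gene C3 (3.8) rose too. Relative to the scaling shift given below, the median of the list was 2.92 (camera adjusted p = 2.37e-05; adjusted p = 0.81 with an estimated correlation). Summed over the list, the RYGB libraries held 10826.9 to 149597 CPM and the sham libraries 3402 to 7589 CPM. Markers of macrophages moved with it: 4 of 17 rose, among them Cd163 (3.15), Csf1r (3.29) and the Kupffer cell lectin Clec4f (3.42), and 11 adjusted over the list alone (camera adjusted p = 0.000227; adjusted p = 0.81 with an estimated correlation).

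Of 18 unfolded protein response genes 7 rose in the liver, and 12 adjusted over the list alone, including the chaperone genes Hspa5 (433 ± 418 to 1630.0 ± 588 CPM, 2.54 ± 0.66), Pdia6 (1.39) and Sdf2l1 (3.37). Camera gave an adjusted p = 0.000411, and an adjusted p = 0.81 with an estimated correlation. Of 13 glucocorticoid response genes 1 rose, Fkbp5 (2.66), and 3 adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.81 with an estimated correlation), a call lost without RYGB 1 (0.16), RYGB 2 (0.0971) or sham 1 (0.107), with median-of-ratios scaling (0.0551) and with the trend with exon length removed (0.0605). Asns, asparagine synthetase (3.38), the scavenger receptor gene Scara5 (5.08) and the methyltransferase gene Nnmt (4.3) rose too.

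Of 25 fatty acid oxidation and PPARA target genes in the liver, 4 fell and none rose, 16 were below and 9 above 0, and 6 fell adjusted over the list alone: Vnn1, pantetheinase, from 1171 ± 182 to 131 ± 157 CPM (−4.04 ± 0.75, adjusted p = 0.0302), Cyp4a14, an omega-hydroxylase, from 6083 ± 3204 to 879 ± 1187 CPM (−4.16), the thioesterase gene Acot2 (−3.43) and Hadhb, of mitochondrial beta-oxidation (−2.56). Camera gave an adjusted p = 0.00754 (adjusted p = 0.837 with an estimated correlation), which became 0.0708 without RYGB 1. Cd36 fell from 1630.0 ± 349 to 359.5 ± 170 CPM (−2.3 ± 0.39), Osbpl3, an oxysterol binding protein, by a log2 value of −4.21, the lipoprotein receptor gene Vldlr by −3.34, the aquaporin gene Aqp4 by −3.48 and Themis by −3.2. Fgf21, the fasting hormone, fell from 6.55 ± 3.74 to 0.82 ± 1.51 CPM (−2.21 ± 0.5, adjusted p = 0.0421).

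In the liver, Cyp2c70, the enzyme that makes mouse muricholic acids, had the smallest adjusted p and rose from 55.6 ± 34.3 to 1835 ± 964 CPM (5.09 ± 0.51, adjusted p = 0.0025); it lies on chromosome 19 from 40153353 to 40187333 (GRCm38). It was 1 of 3 bile acid genes of 23 that rose, also adjusted over the list alone, with the bile salt export pump gene Abcb11 (2.02) and Cyp27a1 (2.79). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 756 ± 209 and 177 ± 201 CPM (−3.43 ± 1.1, adjusted p = 0.0743) and Cyp8b1 at 93.6 ± 50.3 and 83.7 ± 81.0 CPM (adjusted p = 0.463). Of 25 male-biased or growth hormone-induced genes 3 rose (4 rose and 1 fell adjusted over the list alone), Serpina1e (5.35), Serpina3k (3.99) and the complement gene C6 (2.63), the former 2 from families of near-identical genes. Of 11 female-biased genes 3 fell, also adjusted over the list alone: Cyp2b9 from 117 ± 103 to 2.06 ± 2.83 CPM (−5.12 ± 0.83, adjusted p = 0.0243), Acot3 (−3.82) and Cyp4a14. Of 23 cholesterol synthesis genes 3 rose, among them Fdps (2.9) and Nsdhl (2.87), and 7 adjusted over the list alone. Camera called none of these 4 lists. Igf1, Ghr and Hif1a did not pass (adjusted p = 0.188, 0.0737 and 0.195).

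Limma called 209 genes higher and 267 lower of 10285 in the liver, and 513 and 479 with median-of-ratios scaling. That scaling moved the median log2 fold change from 0.263 to 0.0867, a scaling shift of 0.18 (CPM minus scaled). The 476 calls became 9, 14 and 8 without RYGB 2, 3 and 4, 12, 3 and 6 without sham 2, 3 and 4, and 2253, 1046 and 1317 without RYGB 1, RYGB 5 and sham 1. The 5 shallower libraries are 3 RYGB and 2 sham, the others 2 and 2; with the set as a term 1473 genes were higher and 907 lower.

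WAT had the most genes past the test (n = 5 sham and 4 RYGB libraries). All 33 measured oxidative phosphorylation genes rose, over all genes and adjusted over the list alone, with a median of 1.91 relative to the scaling shift given below. Sdhd rose from 133 ± 5.79 to 458 ± 134 CPM (1.72 ± 0.2, adjusted p = 0.000266), Cox5a from 106 ± 15.5 to 565 ± 228 CPM (2.3 ± 0.28), and Uqcrfs1 (2.11) and Atp5b (1.45) rose as well. Camera gave an adjusted p = 8.53e-23, and an adjusted p = 0.448 with an estimated correlation. Of 16 thermogenic adipocyte genes 12 rose and 1 fell, and 13 and 1 adjusted over the list alone (median 2.61 relative to the shift; camera adjusted p = 6.62e-08; adjusted p = 0.448 with an estimated correlation). Ucp1, the uncoupling protein of brown and beige fat, rose from 7.74 ± 15.2 to 822 ± 1406 CPM (5.9 ± 1.31, adjusted p = 0.00553), Cidea, a lipid droplet protein gene, from 4.36 ± 2.45 to 178 ± 146 CPM (4.78 ± 0.52), and Elovl3 (5.05), Cox8b (4.44), the receptor gene Adrb3 (2.33) and Otop1 (3.06) rose too. Ucp1 lies on chromosome 8 from 83290352 to 83298452 (GRCm38).

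Many genes of lipid synthesis rose too in WAT. Of 18 fatty acid synthesis genes 12 rose and none fell, also adjusted over the list alone (median 1.9 relative to the shift; camera adjusted p = 6.6e-09; adjusted p = 0.448 with an estimated correlation). Fasn, on chromosome 11 from 120805846 to 120824547 (GRCm38), rose from 130.5 ± 37.8 to 9631 ± 6595 CPM (5.99 ± 0.4, adjusted p = 1.98e-05), Thrsp from 44.7 ± 17.8 to 1493 ± 1188 CPM (4.76), Elovl6 by 4.14 and the citrate carrier gene Slc25a1 by 3.65. Scd1 did not pass (53820.0 ± 9183 and 78010.0 ± 40210.0 CPM, adjusted p = 0.421). Of 24 cholesterol synthesis genes 11 rose and 1 fell (11 and 2 adjusted over the list alone), among them Acat2 (2.17), Nsdhl (1.85) and Fdps (1.82). Of 24 fatty acid oxidation and PPARA target genes 12 rose and 4 fell, also adjusted over the list alone: Cpt2 (1.45) and Hadha (1.71), of mitochondrial fatty acid oxidation, rose. Both lists were higher by camera (adjusted p = 0.000621 and 0.00145) with an adjusted p = 0.564 with an estimated correlation. Of 27 glycolysis and HIF1 target genes 13 rose, such as Aldoa (2.02), and 6 fell, such as Ndrg1 (−2.33), also adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.512 with an estimated correlation). Glycogen synthase Gys2 (4.21) and transketolase Tkt (3.18) rose.

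**Figure D4:**
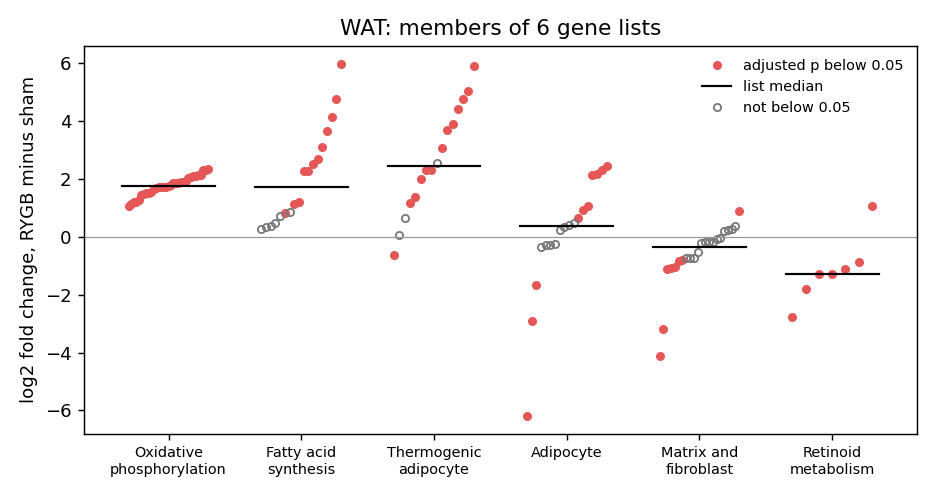
Each point is 1 member of a gene list in WAT, ordered by its log2 fold change of RYGB minus sham (vertical axis) within the list named on the horizontal axis; filled red points have an adjusted p below 0.05, open grey points do not, and black lines are list medians. All 33 oxidative phosphorylation genes are filled and above 0, and the adipocyte list has 7 such points above and 3 below 0.

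The genes with the largest decreases in WAT included Lep, the adipocyte hormone leptin, from 1654 ± 719 to 30.2 ± 19.8 CPM (−6.2 ± 0.85, adjusted p = 0.000526), the imprinted genes Mest, from 1718 ± 741 to 24.1 ± 22.4 CPM (−6.72 ± 0.76), Zim1 (−5.85) and Peg10 (−5.15), and the secreted Wnt pathway genes Sfrp5 (−5.77) and Wisp2 (−6.35). Lep lies on chromosome 6 from 29060220 to 29073877 (GRCm38). Of 18 adipocyte genes 7 rose and 3 fell, also adjusted over the list alone: Gpd1 (2.44), Retn (2.18) and Lpl (1.07) rose, and Lep and Plin4 (−1.68) fell. Fabp4 (adjusted p = 0.125) and Adipoq (1801 ± 240.5 and 2320.0 ± 628 CPM, adjusted p = 0.179) did not pass. Of 22 matrix and fibroblast genes 7 fell and 1 rose, also adjusted over the list alone, with Thbs2 (−4.11), Lox (−3.17) and Dcn (−1.1). Of 7 retinoid genes 6 fell, such as Aldh1a1 (−2.77), and Rbp4 rose (1.07), also adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.448 with an estimated correlation), a call that became 0.0809 without RYGB 3. Camera did not call the adipocyte or matrix lists, nor that of growth hormone and IGF genes. Of 16 growth hormone and IGF genes 8 fell and 1 rose (9 and 1 adjusted over the list alone): Ghr fell from 2468 ± 533 to 988 ± 272 CPM (−1.34 ± 0.25), and Igfbp3 by a log2 value of −2.87. Igf1 did not pass, and Hif1a fell (−0.87 ± 0.21). Cd36 fell from 14540.0 ± 798 to 7666 ± 2245 CPM (−0.96 ± 0.2).

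Some markers of other cells passed the test in WAT, where 40.6% of all genes did. Of 10 smooth muscle and nerve genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with Acta2 from 719 ± 306 to 42.9 ± 19.5 CPM (−3.97) and Synpo2 (−5.08). Of 18 macrophage genes 5 fell, such as Trem2 (−1.32) and Cd68 (−0.79), and 3 rose, such as Marco (2.77), and the B cell chemokine gene Cxcl13 rose (4.93). Of 18 immediate early genes 6 fell, such as Fos (−2.0), and 1 rose, also adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.134, 0.631 and 0.568). Lists of proliferation (6 of 23 rose), unfolded protein response (9 rose and 2 fell of 18), interferon (7 of 23), T and NK cell (2 of 16) and erythrocyte genes (2 of 7) were higher by camera, with adjusted p = 0.611, 0.512, 0.638, 0.687 and 0.611 with an estimated correlation. Adjusted over the lists alone, 2, 10 against 2, 7, 0 and 0 passed. The interferon and T and NK cell calls were lost without RYGB 3 (0.0682 and 0.0553), the latter also without RYGB 4 (0.363) or sham 3 (0.0544), and the erythrocyte call without RYGB 1 (0.133). With median-of-ratios scaling the T and NK cell and erythrocyte calls were lost (0.0882 and 0.07).

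In WAT limma called 1812 genes higher and 3341 lower of 12690, and 2681 and 2593 with median-of-ratios scaling. That scaling moved the median log2 fold change from −0.163 to 0.00465, a scaling shift of −0.17 (CPM minus scaled). Long transcripts were lower in RYGB libraries: from the shortest to the longest of 5 sets of genes by exon length the median log2 fold change went from 0.24 to −0.48. With each library's trend with length removed, 2370 genes were higher and 2406 lower, the unfolded protein response, interferon, T and NK cell and erythrocyte calls were lost (adjusted p = 0.0806, 0.168, 0.379 and 0.468), and 134 called genes changed sign.

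In muscle 0 genes passed the adjusted threshold in limma (n = 4 sham and 4 RYGB libraries; 812 of 11594 at an unadjusted p under 0.05; 13 genes with library weights). The 6 with the smallest adjusted p, 0.0566, were Lep (15.4 ± 9.65 CPM in sham and 0.675 ± 0.499 in RYGB mice, −3.12 ± 0.44), Tmem176b (1.44 ± 0.19), the Rab GTPase regulator Tbc1d1 (132 ± 33.4 and 45.6 ± 4.8 CPM, −1.49 ± 0.21), the desaturase gene Scd2 (26.1 ± 3.9 and 74.5 ± 20.8 CPM), Myo1a and the immunoglobulin gene Igkc. Nos1 and Ccr2 were among the next, with 0.126. Fbxo32, a ubiquitin ligase gene of muscle atrophy (2799 ± 441 and 2099 ± 2456 CPM, adjusted p = 0.761), Pdk4, which limits glucose oxidation (adjusted p = 0.94), Igf1, Ghr and Hif1a did not pass. The count became 24 without RYGB 2, 4 without sham 1 and 1 without RYGB 4 or sham 3.

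Camera called 9 lists higher and 3 lower in muscle, with 0 of their members past the test over all genes. Of 25 fatty acid oxidation and PPARA target genes 24 were below 0 (median −0.55; Ucp3 −0.65 ± 0.2) except Ppargc1a (1.09 ± 0.34), and 0 passed adjusted over the list alone; the adjusted p was 0.365 with an estimated correlation. Lists of adipocyte (3 of 8 fell adjusted over the list alone, Lep included; Fabp4 −0.75 ± 0.24) and oxidative phosphorylation genes were lower, with 0.396 and 0.704 with an estimated correlation. Macrophage (median 0.72; Lyz2 1.09 ± 0.35; 5 of 14 rose adjusted over the list alone), erythrocyte (Hbb-bs 1.95 ± 0.51; 4 of 7) and immediate early genes (Egr1 1.91 ± 0.41; 3 of 18) were higher, each with an adjusted p = 0.365 with an estimated correlation. So were cholesterol and fatty acid synthesis and MHC class II genes (0.365 with an estimated correlation) and interferon, endothelial and glucocorticoid genes (0.704, 0.646 and 0.646). The oxidative phosphorylation list turned its direction without RYGB 2 (0.861) and the interferon list without RYGB 1 (0.897). Of the 12 list calls 7 held without RYGB 4, 9 without RYGB 2, 10 without sham 4, 11 without RYGB 1, RYGB 3, sham 2 or sham 3, and 12 without sham 1.

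Genes past the test in the same direction were counted between tissues, whose libraries come from the same animals. Jejunum and liver shared 56 lower genes, beside 14.6 for independent lists, and 21 higher genes, beside 9.06. Jejunum and WAT shared 228 lower and 155 higher genes (142 and 94.8 for independent lists), and liver and WAT 121 and 50 (69.7 and 27.6). Genes called in opposite directions were 126 higher in jejunum and lower in WAT, 45 the other way, 28 higher in liver and lower in WAT, 17 the other way, and 3 and 5 for jejunum and liver. Log2 fold changes were lower for longer transcripts in all 3 of these tissues (Spearman rho = −0.157 in jejunum, −0.191 in liver and −0.354 in WAT), which the numbers for independent lists leave out of account. The 39 genes past the test in the same direction in 3 tissues were 8 higher and 31 lower; there were 76 with median-of-ratios scaling and 261 with library weights. The former include Asns, Fdps and Nsdhl. The latter include Cd36, the clock genes Per2 and Hlf, the splicing factor gene Srsf5 (−1.2 in jejunum, −2.41 in liver and −1.22 in WAT), the peptide transporter gene Slc15a2 and, in duodenum, jejunum and WAT, Meis2.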

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

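The tests of the share of adipocytes, of a few genes taking much of the CPM, of exon length as the cause of most of the WAT count and of a depth term in liver were chosen only after the result was seen.

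In WAT, 5153 genes passed the test, and the median log2 fold change fell with exon length. With each library's trend with exon length removed, 4776 genes passed, 3627 of them called in the same direction before. This argues against the mean trend with length as the cause of most of the count. Effects of length or RNA quality that differ between single genes would remain after this removal. Of the genes called before, 70.5% kept their call, a share that leaves the planned test of length undecided. For the others exon length and surgery cannot be told apart, since the trend itself differs between the groups. A few genes taking much of the CPM would not leave 85.5% of the calls with another scaling. The excess of lower genes was not kept, as 1812 higher and 3341 lower became 2681 and 2593, so that excess depends on the scaling. A change in the share of adipocytes stays open, since 7 adipocyte genes rose and 3 fell, which decides nothing. A difference due to the surgery, or to the restricted rations of the sham mice, stays open too.

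Ileum sham 4 had a median CPM of 33.9 and lay far from the other sham libraries. Its correlation with the mean of the other ileum sham libraries was 0.803, against 0.748 with duodenum and 0.765 with jejunum. The first was 0.0377 above the higher of the others. The other ileum sham libraries reached 0.945 to 0.983 with ileum and 0.9 to 0.926 with jejunum. This order argues against a library of duodenum or jejunum, though sham 4 was less like every segment. No gut segment beyond the ileum was sampled, so a library of such a segment stays open. All 10 lists of crypt, secretory, immune, vessel and stroma markers had a median difference above 0 from the other sham libraries, from 4.94 (stem cell), 4.14 (proliferation) and 2.85 (goblet) down to 0.9 (endothelial) and 0.15 (T and NK cell) on the log2 scale, but 0 of 17 T and NK cell, 0 of 12 B and plasma cell and 2 of 14 macrophage genes lay above all other sham libraries. More crypt cells in the scraping may account for the higher crypt and secretory markers. The B and plasma cell and macrophage lists had median differences of 1.63 and 0.496, though few of their genes lay above all other sham libraries. These values leave open whether there were more lamina propria cells. No biological explanation was tested, as the library shares its group with the others.

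The liver libraries fall into 5 of low and 4 of higher depth, and 1298 genes differed between these sets. With the set as a term 99.8% of the 476 liver calls held. The sets hold 3 RYGB and 2 sham, and 2 RYGB and 2 sham libraries, so the term could hardly change these calls and the share decides nothing. Only that near balance leaves a shift shared by all libraries of a set little room as the source of these calls. It does not cover differences within a set. Sham 3 and 4, both of the higher depth, had a median CPM of 7.2 and 8.6, with 8419 and 8708 genes at 1 CPM or more. The other livers had 12.6 to 18.9, and 9268 to 9983 genes. What sets sham 3 and 4 apart was not tested. Of the 476 genes 100% had the same sign in both sets. As they were picked over all 9 libraries, this leaves open whether 1 set gives most of the difference. A difference due to the surgery, or to the restricted rations of the sham mice, stays open, next to other differences between single livers.

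Random splits of the libraries into groups of the same sizes were counted. In duodenum 3 of 100 splits gave as many genes as the real one (38; highest other 311, with sham 5 on the side of RYGB), in jejunum 1 of 100 (1390; 92), in liver 2 of 100 (476; 1370), in WAT 1 of 100 (5153; 0) and for jejunum minus duodenum 1 of 56 (256; 23). For jejunum and WAT no other split drawn gave as many genes, which makes chance unlikely. For the difference between the segments no other split did either. The only other one with any genes (23) set the sham animals W11, W12 and W14 apart. Those gave the sham duodenum libraries rich in pancreatic transcripts, so contamination and surgery may both have a part in that difference. For duodenum and liver the share of such splits is also under 0.05, but the real split is not the one with the most genes. The split with the most genes moved only sham 5 in duodenum. In liver it exchanged only RYGB 1 and sham 1, with RYGB 2 to 5 and sham 1 against RYGB 1 and sham 2 to 4. Both keep most of the surgery labels, so single atypical libraries or a structure of the samples beside the surgery may give them. The liver split also goes partly with depth, since of the 5 libraries of low depth only sham 2 lies on the side of RYGB 1. Which of these holds was not tested. In muscle the real count was 0 in limma (812 at an unadjusted p under 0.05; highest other 4), which any split reaches, so that the 35 of 35 splits decide nothing.

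For the genes named in the text, 1 library lay far from the rest of its group in 40 of 463 groups (8.64%, the median CPM above included), where chance gives about 1 in 20. In duodenum this held for sham 5 with Prc1 (3.7 CPM) and Arntl (21.6 CPM). In jejunum it held for RYGB 4 with Ugt2b5 (19.4), Anpep (13525.2), Cd36 (720.0), Abcg5 (581.8) and Aldh1a1 (875.6), for RYGB 1 with Dbp (22.8), for RYGB 2 with Slc10a2 (7.7) and for RYGB 3 with Meis2 (0.2), all in CPM. Among the sham jejunum libraries it held for sham 3 with Cd36 (2394.6), Pfkp (123.7) and Slc2a1 (31.8), for sham 5 with Hif1a (209.9) and Ghr (23.9) and for sham 1 with Rrm2 (7.4 CPM). In ileum sham 4 stood apart for Mt2 (10.4), Gcg (135.4) and Slc5a1 (858 CPM).

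In liver the libraries far from their group were RYGB 1 for Serpina3k (3614.8 CPM), RYGB 5 for Osbpl3 (28.6) and Fgf21 (3.5), and sham 4 for Acot2 (106.7). In WAT they were sham 3 for Cxcl13 (3.5) and Igf1 (257), sham 5 for Lep (436.2) and Aldh1a1 (240.7), sham 4 for Ucp1 (35.0), RYGB 2 for Lep (1.2), RYGB 4 for Ghr (580.3) and RYGB 3 for Aldoa (652.1 CPM). In muscle they were sham 1 for Myo1a (0.9), Igkc (63.2) and Egr1 (13.7), RYGB 4 for Ccr2 (13.7), RYGB 2 for Fabp4 (78.7) and Fbxo32 (5779.7), sham 3 for Ghr (188.8) and sham 4 for Fbxo32 (3458.2 CPM).

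The RYGB difference was not the same in jejunum and duodenum for 17 of 83 named genes. Jejunum minus duodenum, on the log2 scale, it was −3.58 for Cd36, 5.91 for Slc40a1, 6.11 for Akp3, −3.41 for Akr1c19, 3.33 for Slc37a2, −3.32 for Slc6a20a, 1.74 for Pklr, −3.59 for Cubn and 1.82 for Elovl6. For Fdft1 it was 2.19, for Slc15a1 −1.31, for Ncoa4 2.2, for Ugt2b5 −3.17, for Cyp3a25 −2.0, for Cyp4a10 −3.15, for Gpi1 1.41 and for Aqp1 −4.93.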

How the results depend on the processing

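The tests with a pseudocount of 0.1 for the counts, scaling for the lists, a mean CPM minimum, library weights, a depth term, the exon length trend removed and the duodenum without pancreatic libraries were chosen only after the result was seen; the planned count-based tests and the setting without a filter were not run, as the deposited tables hold filtered CPM.

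Of 3531 values of named genes under the alternatives, 2922 kept direction and side of the threshold, 493 no longer passed, 81 newly passed and 35 turned direction. Of 66 list calls 61 held with median-of-ratios scaling, 58 with the exon length trend removed and 0 with an estimated correlation, and 494 of 550 held with 1 library left out. Low depth limits genes of few CPM in the 5 shallow livers. Except where fewer libraries or genes were tested, the cause was not tested.

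Counts of genes higher and lower that moved by over 1.5 times were as follows. With median-of-ratios scaling: 37 lower in duodenum, 513 and 479 in liver, 119 lower for jejunum minus duodenum, and 76 genes shared by 3 tissues. With the CPM minimum: 68 and 37 in duodenum. With library weights: 1576 and 564 in duodenum, 1 higher in ileum, 1583 and 1675 in liver, 8 and 5 in muscle, 1266 and 2094 for jejunum minus duodenum, and 261 shared genes. With the exon length trend removed: 353 and 572 in liver and 2 and 2 in muscle. With a pseudocount of 0.1 muscle had 1 lower gene, with the depth term liver had 1473 and 907, and without pancreatic libraries duodenum had 0 and 0 in limma (378 at an unadjusted p under 0.05).

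Replicate numbers do not pair the animals, as the animal codes show. Libraries of the same number correlated at −0.317 to 0.556 in duodenum, −0.253 to 0.376 in ileum and −0.352 to 0.102 in liver across genes. In duodenum 2 of 4 such pairs lay above 0.1, so these values do not exclude something else shared by libraries of the same number. With the replicate number as a block the counts were 308 and 142 in duodenum, 192 and 263 in jejunum, 418 and 175 in ileum (on 1 residual degree of freedom), 5 and 2 in liver and 1 and 1 in muscle. With that block Slc2a1 and Igf1 in ileum turned to 0.84 and 0.33, and Igf1 in WAT to 0.002.

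With 1 library left out, genes higher and lower ranged over 0 to 820 and 1 to 162 in duodenum, 225 to 1079 and 259 to 1180 in jejunum, 0 to 28 and 0 to 18 in ileum, 3 to 1379 and 0 to 874 in liver, 1391 to 2130 and 2545 to 4021 in WAT, 0 to 14 and 0 to 10 in muscle, and 16 to 73 and 43 to 249 for jejunum minus duodenum, and list calls over 56 to 72. Log2 fold changes that turned ranged from −0.395 to 0.69 for Slc2a1 in duodenum, −0.12 to 0.35 for Slc5a1 in jejunum, −1.711 to 0.705 for Slc10a2, −0.89 to 0.73 for Slc2a1, −0.715 to 0.211 for Igf1 and −0.45 to 0.565 for Hif1a in ileum, −0.381 to 0.203 for Igf1 in WAT, and −0.064 to 0.43 for Ghr, −0.029 to 0.265 for Hif1a and −0.702 to 0.079 for Pdk4 in muscle. Adjusted p of lists that turned ranged from 6.21e-06 to 0.876 (goblet), 4.08e-06 to 0.766 (glycolysis) and 3.12e-06 to 0.596 (lipid absorption) in ileum, and 6.33e-05 to 0.897 (interferon) and 7.38e-05 to 0.861 (oxidative phosphorylation) in muscle.

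Other turns of direction, none past the threshold, were Slc2a1 in duodenum (−0.009 with scaling, −0.413 with weights, −0.001 with exon length) and in ileum (0.022, 0.62 and 0.021), Igf1 and Hif1a in ileum with weights (0.17 and −0.039), Adipoq in WAT with exon length (−0.005), and Igf1 in WAT (0.17 with scaling, 0.01 with weights, 0.45 with exon length).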

Other observations

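The test of heat shock and cold-response genes was chosen only after the shared genes were seen.

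Single clock genes differed between the groups in several tissues. In liver 2 of 15 rose and 2 fell (2 and 5 adjusted over the list alone): Arntl, a core activator of the clock, rose from 3.4 ± 1.16 to 20.46 ± 10.1 CPM (2.19 ± 0.41), and its output gene Hlf fell from 323 ± 72.9 to 86.0 ± 44.8 CPM (−2.02 ± 0.37). In WAT 7 of 17 fell and 1 rose, also adjusted over the list alone, among them Per2 (−1.46 ± 0.32) and Hlf (−1.08 ± 0.32), and Per2 fell in jejunum (−1.68 ± 0.45) and in liver (−1.64 ± 0.42). Camera called the list in neither liver nor WAT (adjusted p = 0.321 and 0.151), and 40.6% of all WAT genes were called. In muscle 0 of 18 passed in limma. All mice were killed at 10 am, per the labels; whether the groups differed in feeding time before the fast is not given.

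For the genes lower in 3 tissues, a lower body temperature of the food-restricted sham mice was weighed. It would need Cirbp and Rbm3, which rise in the cold, to be lower and heat shock genes higher after RYGB in jejunum, liver and WAT. This held in 0 of the 3 tissues. Heat shock genes had medians of 0.71, 0.69 and 0.7, with 2, 1 and 8 rising and 0, 1 and 0 falling. Cirbp fell in WAT (−0.88 ± 0.18, adjusted p = 0.00368) and stood at 0.005 ± 0.27 in jejunum and 0.57 ± 0.51 in liver, and Rbm3 at 0.08 ± 0.23, −0.15 ± 0.23 and −0.94 ± 0.43 in WAT, jejunum and liver. Body temperature was not recorded in the labels, and these values leave the explanation open.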
